A study of Homo sapiens with 18 samples.

How the data were processed

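PolyA RNA was sequenced from 18 libraries of U2OS, a human osteosarcoma cell line, in 6 groups of 3 libraries. The labels call the libraries of a group biological replicates. Untreated cells carried integrated mCherry, mCherry-EWS-FLI1, mCherry-EWS-FLI1mut or mCherry-EWS(YS37)-FLI1. EWS-FLI1 is the fusion transcription factor of Ewing sarcoma. The remaining 6 libraries came from mCherry-EWS-FLI1 cells treated with 7.5 µM LY2835219 (abemaciclib, an inhibitor of the cell cycle kinases CDK4 and CDK6) for 6 h or 24 h, the times that the titles, the sample characteristics and the series design state. The treatment protocol of the same labels gives other times, so the labels conflict there. The labels do not say what the EWS-FLI1mut change is, whether each line was a clone or a pool, or whether a vehicle was added to untreated cells, and they name 2 library kits without saying which library used which. No independently made lines of a construct are labelled, so p values and standard errors do not cover differences between such lines.

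The authors deposited 1 transcript table per library. Per the file headers, each table holds kallisto estimated counts (expected counts, not normalized), TPM (length-normalized transcript shares) and an effective transcript length in bases, a unit other than an expression level. The authors state kallisto version 0.46, CASAVA and hg38 in the processing notes. They do not state the transcript set, the index options or the strandedness of the libraries. Every table lists 188753 transcripts. The estimated counts were not whole numbers and the TPM of each library had the same sum, both checked on the values.

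Transcripts were assigned to genes by versionless Ensembl transcript identifier with the GENCODE 29 annotation of hg38, which matched 169797 transcripts. Between 2.59% and 2.74% of a library's estimated counts lay on transcripts without a match and were left out. Estimated counts were summed per gene and rounded. Total estimated counts ranged from 16261034 to 20270637 per library, and 19685 to 20457 genes held at least 1 count. Standard errors of log2 fold changes come from 1 fit of all 18 libraries. They reflect a spread among libraries pooled over the 6 groups, not that of the compared groups alone.

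Differential expression was tested with edgeR 4.0.16 in R 4.3.3. TMM factors, filterByExpr by group and 1 quasi-likelihood fit of all 18 libraries with 1 mean per group left 16785 genes and 12 residual degrees of freedom, with a biological coefficient of variation of 8.77%. The p values of each comparison were adjusted by Benjamini-Hochberg over all genes tested, and a gene is called at an adjusted p under 0.05. Calls that also had an absolute log2 fold change of at least 1 were counted apart. Log2 fold changes are given with a standard error, computed as the absolute log2 fold change over the square root of its quasi-likelihood F statistic. Levels are given as TMM-scaled CPM with the standard deviation over 3 libraries.

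The 8 comparisons, the tests, the gene lists and the rule for naming genes were chosen before the data were examined. The rule named FLI1 and EWSR1, and in each comparison the 8 rising and 8 falling protein-coding genes with the largest log2 fold changes. These had to be called, to average at least 5 CPM in the higher group and to have no overlap between the libraries of the groups, a separation that chance alone gives for 10% of genes with 3 against 3 libraries. It further named up to 4 called members per list, or the 2 most abundant members where none was called, and for pairs of comparisons the 8 genes called in both with the largest product of fold changes. Not every gene under the rule is printed, and the results of some are not reported here.

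The 21 gene lists were written from general knowledge: genes that the Ewing sarcoma literature reports as activated or as repressed by EWS-FLI1, CDK4/6-RB machinery, E2F/G1-S genes, G2/M genes, lysosomal proteins, V-ATPase subunits, autophagy and MiT/TFE genes, cholesterol synthesis and uptake, ATF4/integrated stress response, ER chaperones and unfolded protein response, p53 targets, interferon-stimulated genes, NF-kB and inflammatory genes, osteoblast and bone matrix genes, neuronal genes, epithelial, blood cell and endothelial markers, immediate early genes, and replication-dependent histones as a sign of RNA quality. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted by Benjamini-Hochberg over the lists of a comparison. An estimated correlation and fry, whose directional test asks whether the genes of a list move on balance in a single direction and whose mixed test asks whether they change in either direction, stood beside it. Several genes stand in more than 1 list, CDKN1A in 3 of them. A further 19 gene families, defined by symbol, of which 17 had at least 5 tested members and were tested, were chosen after the main results were seen but before their own values were.

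Pairs of comparisons that share a control group were set beside 20 simulated draws of unchanged groups with the same shared libraries, since a shared group alone gives a correlation. A group of 3 libraries cannot be parted into 2 sets with replicates, so the share of an overlap that comes from shared controls was estimated from the simulation alone. The simulated draws hold noise between libraries only, so a shared group that stands apart as a whole is not covered. Counts expected by chance assume independent lists of calls. Reads that transcripts of other genes could explain were assessed for the 352 genes under the naming rule and the lists. For each gene, the 31-base sequences of its most abundant reference transcript were searched for in transcripts of other genes. Over 50% of these sequences were shared for 22 of the genes.

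The edgeR test was tested on simulated data: counts were drawn with the mean and dispersion of each gene and the size of each library, and 200 genes were changed between EWS-FLI1 and mCherry by a known fold. A list of 30 further genes was raised 1.3-fold, and their calls count among all calls but not as false calls. It called 75% of genes changed by 2-fold and 61% of genes changed by 1.5-fold, with 5 false calls, 3.33% of all calls. DESeq2 1.42.0 called 77% and 63% with 16 false calls, and limma on log2(TPM + 1) called 57% and 31% with 3.

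Alternatives were other scalings (DESeq2 size factors and upper quartile), no low-count filter or a stricter one (1 CPM in 3 libraries), fits of only the libraries compared, a block for the replicate number, DESeq2, a test against an absolute log2 fold change of 0.5 (glmTreat), offsets from the effective transcript length, limma on log2(TPM + 1), protein-coding genes only, and each library left out in turn. The scaling without factors and the fit without mitochondrial genes and the 100 genes with the most counts were chosen after seeing the data. Replicate numbers paired the libraries weakly at most: same-numbered libraries had correlations of log2 residuals between -0.04 and 0.06. In EWS-FLI1mut vs mCherry, all 6 libraries correlated best with their own number (mean 0.054, and -0.027 for other numbers). A weak pairing is not excluded there. The mCherry sequence is not in a human reference and was not analysed here.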

Results

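The 18 libraries separated first by treatment: the first principal component held 42.4% of the variance and set the 6 h LY2835219 libraries apart, and the second held 14.3% and set the 24 h libraries apart. The share of reads from mitochondrial genes was 6.14 ± 0.146% at 6 h and 6.16 ± 0.380% at 24 h, against 4.80 ± 0.277% in untreated EWS-FLI1 cells and 4.73 ± 0.279% in mCherry cells. Values after a log2 fold change are standard errors, those after a level are standard deviations, and each group had 3 libraries. With no scaling factors the median log2 fold change of all genes was -0.27 at 6 h against untreated cells and 0.31 at 24 h against 6 h, and 0.15 for the latter with upper-quartile scaling. Changes under LY2835219 are therefore relative to the TMM scaling, under which these medians were -0.02 and 0.05.

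FLI1 and EWSR1, the genes whose parts form the fusion, showed the constructs. FLI1 (ENSG00000151702, chromosome 11, 128686535 to 128813267 of hg38, plus strand) averaged 0.547 ± 0.563 CPM in mCherry cells, 247 ± 16.3 with EWS-FLI1, 642 ± 19.9 with EWS-FLI1mut and 1019 ± 44.0 with EWS(YS37)-FLI1. EWS-FLI1 cells thus held less FLI1 RNA than cells with EWS-FLI1mut (log2 -1.38 ± 0.09) or with the YS37 construct (-2.04 ± 0.09). EWSR1 (ENSG00000182944, chromosome 22, 29268009 to 29300525) rose over mCherry by log2 1.12 ± 0.05, 1.79 ± 0.05 and 1.48 ± 0.05 in the same order of constructs. On the TPM scale the difference was larger, from 222 ± 11.9 in mCherry cells to 1388 ± 129, 2262 ± 200.2 and 1609 ± 24.2. FLI1 was higher at 6 h of LY2835219 than in untreated cells (0.72 ± 0.09, adjusted p = 1.34e-07). On the TPM scale the log2 change was 0.34, from 139 ± 12.7 to 175 ± 8.18. At 24 h FLI1 was not called (-0.07 ± 0.09, adjusted p = 0.57). Of the 449 stretches of 31 bases in the most abundant EWSR1 transcript, 29% occur in other genes. The reads do not separate the transgene from the endogenous genes.

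**Figure D1:**
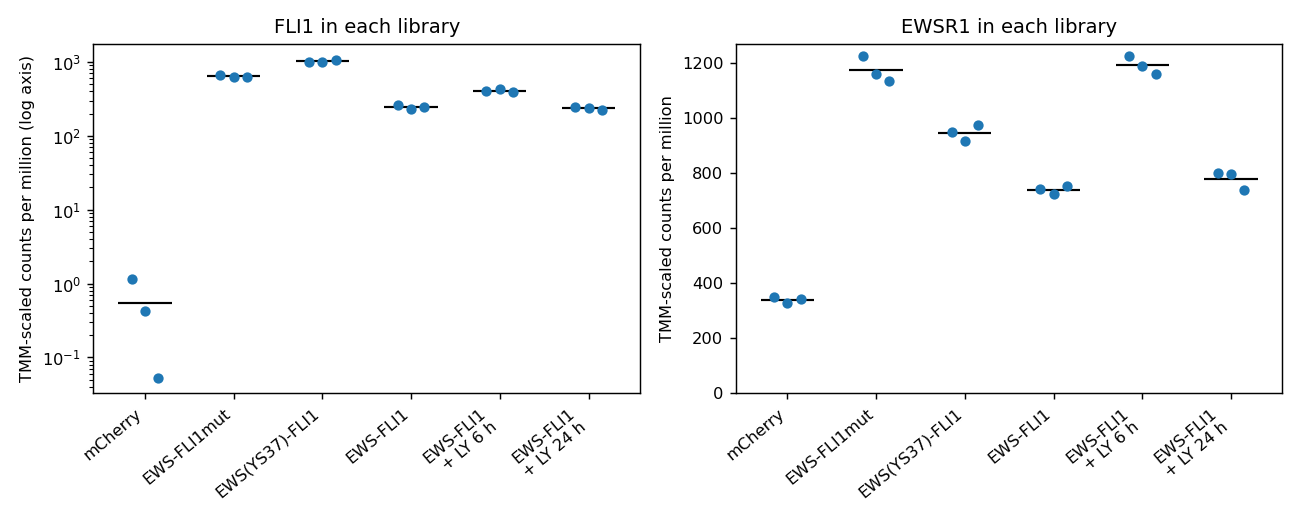
FLI1 (left, log axis) and EWSR1 (right) in TMM-scaled CPM for the 6 groups, with 1 point per library and a line at the mean of 3 libraries. FLI1 was lowest in mCherry cells (0.547) and highest with EWS(YS37)-FLI1 (1019).

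In EWS-FLI1 cells, cell cycle genes were lower than in mCherry cells and immediate early genes higher. Among the strongest rises were BGN, the matrix proteoglycan biglycan (log2 2.97 ± 0.32), CDH5, the endothelial cadherin (2.79 ± 0.27), LRRC32 (2.52 ± 0.33), CD248 (2.44 ± 0.27), the matrix protease MMP9 (2.27 ± 0.24) and CDKN2B, which encodes the CDK4/6 inhibitor p15 (2.28 ± 0.27, from 2.77 to 13.5 CPM). FHOD3, a formin of muscle, fell (-1.76 ± 0.16), as did the potassium channel KCNK10 (-1.75 ± 0.26) and STC1, the secreted stanniocalcin (-1.52 ± 0.21). In all, 1866 genes rose and 1670 fell, 21.1% of those tested, and 179 and 141 of them changed by at least 1 on the log2 scale. Calls numbered 1696 with transcript-length offsets, 1679 with limma on log2(TPM + 1) and 183 when tested against a log2 change of 0.5.

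The list of genes that the Ewing sarcoma literature calls repressed by EWS-FLI1 rose in these cells: 14 of 17 tested members rose and 0 fell, 15 and 0 adjusted over the list alone (camera adjusted p = 3.16e-17). CRYAB, a small heat shock protein (1.62 ± 0.08), and CTGF, a secreted matricellular protein (1.03 ± 0.06), were among them. Of 28 genes of the literature's activated list, 4 rose and 4 fell, 4 and 4 adjusted over the list alone (adjusted p = 0.612). PAPPA was among the rises (0.94 ± 0.13), and CAV1 (-1.06 ± 0.08) and UPP1 (-0.61 ± 0.08) were among the falls. In the E2F/G1-S list, 0 of 37 rose and 30 fell, 32 adjusted over the list alone (adjusted p = 5.37e-23). Examples were the activator E2F2 (-0.82 ± 0.12), the DNA repair gene BRCA1 (-0.69 ± 0.08) and thymidine kinase TK1 (-0.58 ± 0.06). Of the G2/M genes, 23 of 33 fell and 0 rose, 27 adjusted over the list alone (adjusted p = 1.31e-14). KIF11, a mitotic kinesin, was among them (-0.49 ± 0.07). The CDK4/6-RB machinery had 5 rises and 2 falls among 14, 5 and 4 adjusted over the list alone (adjusted p = 0.151); CDK6 rose by 0.92 ± 0.08.

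Immediate early genes, which respond within minutes to growth signals, rose in 9 of 13 and fell in 0, 9 and 0 adjusted over the list alone (adjusted p = 8.01e-08). Among them were FOS (0.94 ± 0.14) and EGR1 (0.87 ± 0.09). NF-kB and inflammatory genes rose in 10 of 17 and fell in 0, 12 and 1 adjusted over the list alone (adjusted p = 5.52e-05; adjusted p = 0.0539 with an estimated correlation). The chemokine CXCL8 rose by 1.93 ± 0.33 and the NF-kB subunit RELB by 1.22 ± 0.12. Cholesterol genes rose in 10 of 24 and fell in 0, 12 and 1 adjusted over the list alone (adjusted p = 8.19e-05). Epithelial markers rose in 4 of 8 and fell in 0, 4 and 0 adjusted over the list alone (adjusted p = 0.00131). KRT14 was among them (0.93 ± 0.18). Lysosomal proteins rose in 15 of 36 and fell in 5, 18 and 7 adjusted over the list alone (adjusted p = 0.00106; adjusted p = 0.329 with an estimated correlation). CTSF, a cathepsin, was among them (0.84 ± 0.12). Of the ATF4/integrated stress response list, 3 of 25 rose and 10 fell, 4 and 12 adjusted over the list alone (adjusted p = 0.00195; adjusted p = 0.183 with an estimated correlation). SLC7A11, a cystine transporter, was among them (-1.02 ± 0.08).

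The remaining lists held members of both directions or few calls in EWS-FLI1 cells and are given as rises and falls with the camera adjusted p. V-ATPase subunits had 3 and 2 of 16 (0.496), autophagy and MiT/TFE genes 8 and 4 of 29 (0.0979; OPTN 0.76 ± 0.07), ER chaperones 5 and 2 of 16 (0.380; HERPUD1 0.57 ± 0.09), and p53 targets 5 and 3 of 22 (0.846; PLK2 -1.12 ± 0.07). Interferon-stimulated genes had 0 and 5 of 26 (0.0577; IFI44 -1.19 ± 0.15), osteoblast genes 6 and 3 of 15 (0.309; COL1A1 0.67 ± 0.09, SPP1 -1.30 ± 0.22) and neuronal genes 5 and 4 of 15 (0.206; CHGB 1.27 ± 0.27). Endothelial markers had 1 and 0 of 10 (0.221; CDH5) and replication-dependent histones 2 and 0 of 10 (0.253; HIST2H2BE 0.43 ± 0.08). The blood cell list held 3 tested genes, too few for a list test, and CD74 (0.24 ± 0.60), PTPRC (0.04 ± 0.48) and ITGAM (0.19 ± 0.74) were not called.

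EWS-FLI1mut cells differed less from mCherry cells in number of calls: 592 genes rose and 608 fell, 7.15% of those tested, with 61 and 28 past 1 on the log2 scale. The secreted glycoprotein CHI3L1 rose (2.61 ± 0.38), with the neurotrophin receptor NTRK2 (1.99 ± 0.28), RGS4, a regulator of G protein signalling (1.67 ± 0.19), and the growth factor EREG (1.63 ± 0.25). TNFAIP6 fell (-1.37 ± 0.22), as did LRRC15 (-1.20 ± 0.15) and the aldehyde oxidase AOX1 (-1.07 ± 0.13). Of 22 p53 targets, 12 rose and 0 fell, 13 and 0 adjusted over the list alone (adjusted p = 1.17e-09). These included the cytokine GDF15 (1.26 ± 0.20) and TP53INP1 (0.55 ± 0.09). Immediate early genes rose in 7 of 13 and fell in 0, 10 and 0 adjusted over the list alone (adjusted p = 9.8e-08). Among them were FOS (0.88 ± 0.14) and EGR1 (0.85 ± 0.09). ER chaperones fell in 5 of 16 and rose in 0, 10 falls adjusted over the list alone (adjusted p = 3.42e-06). G2/M genes fell in 10 and rose in 0 of 33, 13 adjusted over the list alone (adjusted p = 2.23e-10; adjusted p = 0.119 with an estimated correlation).

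Of the literature's repressed list, 6 of 17 genes rose with EWS-FLI1mut and 2 fell, 7 and 2 adjusted over the list alone (adjusted p = 2.15e-05; adjusted p = 0.117 with an estimated correlation). TIMP1, an inhibitor of metalloproteinases, rose (0.81 ± 0.11), as did CTGF (0.74 ± 0.06), and the fibrillar collagen COL3A1 fell (-0.66 ± 0.10). Lysosomal proteins rose in 8 of 36 and fell in 0 (adjusted p = 0.000577; adjusted p = 0.319 with an estimated correlation). Examples were the cathepsin CTSB (0.69 ± 0.07) and the sterol carrier NPC2 (0.64 ± 0.09). The ATF4/integrated stress response list fell in 8 of 25 and rose in 2 (adjusted p = 0.00504; adjusted p = 0.319 with an estimated correlation), a call lost without mCherry replicate 1 (0.117). Replication-dependent histones rose in 2 of 10 and fell in 0 (adjusted p = 0.0402; adjusted p = 0.333 with an estimated correlation), a call lost without EWS-FLI1mut replicate 2 (0.124) or 3 (0.0744) or mCherry replicate 1 (0.0534) or 2 (0.11). The number of calls was 667 without mCherry replicate 2, 739 without mCherry replicate 3, 684 without EWS-FLI1mut replicate 1, 684 without replicate 2 and 766 without replicate 3. It was 359 with length offsets, 384 with limma on log2(TPM + 1) and 29 against a log2 change of 0.5.

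In EWS(YS37)-FLI1 cells, NF-kB and inflammatory genes were higher than in mCherry cells. CSF2RB, the shared receptor chain for GM-CSF and IL-3, was at 0 counts in the 3 mCherry libraries and at 391 counts with YS37, at least 122-fold higher with a floor of 3 counts over the group. MC5R, a melanocortin receptor (4.63 ± 0.47), ESM1, an endothelial proteoglycan (3.64 ± 0.30), CDH5 (3.32 ± 0.27), the endothelial receptor ROBO4 (3.22 ± 0.29) and the tight junction gene CLDN1 (3.01 ± 0.13) rose. MYOCD, a coactivator of smooth muscle genes, fell (-3.86 ± 0.32), with COL3A1 (-3.26 ± 0.12), the chemokine CXCL14 (-2.97 ± 0.12), WNT11 (-2.54 ± 0.30) and the serotonin receptor HTR2A (-2.38 ± 0.21). In all, 1937 genes rose and 1709 fell, 236 and 247 past 1 on the log2 scale. Calls numbered 1965 with length offsets, 1907 with limma on log2(TPM + 1) and 404 against a log2 change of 0.5.

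NF-kB and inflammatory genes rose in 12 of 17 with YS37 and fell in 0, 12 and 0 adjusted over the list alone (adjusted p = 6.67e-09). These included IL6 (2.98 ± 0.54), the chemokine CCL2 (2.76 ± 0.24) and RELB (2.19 ± 0.11). The ATF4/integrated stress response list had 16 rises and 2 falls among 25, 17 and 3 adjusted over the list alone (adjusted p = 7.1e-06; adjusted p = 0.106 with an estimated correlation). GDF15 rose (1.52 ± 0.20), as did PPP1R15A, a phosphatase subunit that acts on eIF2alpha (1.01 ± 0.07), while SLC7A11 fell (-0.99 ± 0.08). Of 22 p53 targets, 11 rose and 1 fell, 12 and 2 adjusted over the list alone (adjusted p = 1.85e-05; adjusted p = 0.0553 with an estimated correlation). Among them were the CDK inhibitor CDKN1A (0.56 ± 0.06) and PLK3 (1.07 ± 0.08). G2/M genes fell in 13 of 33 and rose in 1, 13 and 3 adjusted over the list alone (adjusted p = 0.00247; adjusted p = 0.433 with an estimated correlation). CENPF, a kinetochore gene, was among them (-0.71 ± 0.09). Immediate early genes rose in 6 of 13 and fell in 1 (adjusted p = 0.00128; adjusted p = 0.141 with an estimated correlation). These included FOSL1 (1.31 ± 0.09) and MYC (0.81 ± 0.07).

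The literature's repressed list split with YS37: 9 of 17 rose and 4 fell, 9 and 4 adjusted over the list alone (adjusted p = 0.0121; adjusted p = 0.306 with an estimated correlation), with CYR61 (1.42 ± 0.06) and TAGLN (1.04 ± 0.10) among the rises and COL3A1 and PHLDA1 (-0.94 ± 0.15) among the falls. Among the epithelial markers 2 rose and 4 fell of 8 (adjusted p = 0.891): the basal keratin KRT14 fell (-2.35 ± 0.22) and the simple epithelial keratin KRT18 rose (0.73 ± 0.05). Other genes share 40% of the 31-base stretches of KRT14 and 67.5% of those of KRT18, so reads of keratin pseudogenes are not excluded for either. Interferon-stimulated genes had 5 rises and 6 falls among 26 (adjusted p = 0.825), with IFIT3 (1.85 ± 0.37) and IFIT2 (1.82 ± 0.41) up. The endothelial list had 3 rises and 1 fall among 10 (adjusted p = 0.428). Of the blood cell list, the myeloid integrin ITGAM was called (2.35 ± 0.66, adjusted p = 0.012), though not without mCherry replicate 2 (adjusted p = 0.0528) or replicate 3 (0.0584), and PTPRC (-0.49 ± 0.49) and CD74 (-1.22 ± 0.67) were not. Replication-dependent histones, listed as a sign of RNA quality, fell in 6 of 10 with YS37 and rose in 0 (adjusted p = 0.00776, and 0.306 with an estimated correlation). Whether RNA quality or something else moved these genes was not tested.

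Set directly against EWS-FLI1mut, EWS-FLI1 cells were higher in CDH5 (3.67 ± 0.29), the calpain CAPN6 (2.89 ± 0.28), BGN (2.67 ± 0.30) and KIAA1210 (2.56 ± 0.12). They were lower in the Wnt agonist RSPO3 (-2.45 ± 0.36), NTRK2 (-1.96 ± 0.28), EREG (-1.88 ± 0.25) and the homeobox gene HOXA13 (-1.88 ± 0.22). E2F/G1-S genes were lower in 28 of 37 and higher in 0, 30 lower adjusted over the list alone (adjusted p = 2.72e-20). Among them were E2F2 (-1.02 ± 0.12) and CCNE1, cyclin E1 (-0.67 ± 0.08). Of 22 p53 targets, 10 were lower and 0 higher, 12 and 0 adjusted over the list alone (adjusted p = 2e-05). Examples were PLK2 (-1.11 ± 0.07) and FAS, the death receptor (-0.93 ± 0.16). The literature's repressed list was higher in 10 of 17 and lower in 2, 12 and 2 adjusted over the list alone (adjusted p = 5.07e-08). These included CRYAB (2.07 ± 0.08) and COL3A1 (1.04 ± 0.10). Cholesterol genes were higher in 10 of 24 and lower in 0, 11 and 0 adjusted over the list alone (adjusted p = 7.32e-07). SQLE, an enzyme of the pathway, was among them (0.54 ± 0.07). ER chaperones were higher in 8 of 16 and lower in 0, 8 adjusted over the list alone (adjusted p = 3.7e-05; adjusted p = 0.0542 with an estimated correlation), with HERPUD1 (0.88 ± 0.09). A total of 1474 genes were higher and 1260 lower; 1264 were called with length offsets, 1276 with limma on log2(TPM + 1) and 192 against a log2 change of 0.5.

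Set directly against EWS(YS37)-FLI1, EWS-FLI1 cells were higher in R3HDML (4.76 ± 0.34), KIAA1210 (3.88 ± 0.13), CD248 (3.76 ± 0.30), CAPN6 (3.67 ± 0.30) and COL3A1 (3.65 ± 0.12). They were lower in the leukocyte integrin ITGAX (-2.99 ± 0.24), ROBO4 (-3.03 ± 0.29), ESM1 (-2.39 ± 0.27) and LAMP3 (-2.34 ± 0.19). Of the ATF4/integrated stress response list, 19 of 25 were lower and 1 higher, 19 and 1 adjusted over the list alone (adjusted p = 2.02e-10). Examples were the mitochondrial serine enzyme SHMT2 (-0.79 ± 0.05) and ATF3 (-0.82 ± 0.14). E2F/G1-S genes were lower in 29 of 37 and higher in 0, 30 lower adjusted over the list alone (adjusted p = 4.79e-13). CDC25A, a phosphatase, was among them (-0.72 ± 0.07). The literature's repressed list was higher in 11 of 17 and lower in 3, 13 and 3 adjusted over the list alone (adjusted p = 3.17e-06; adjusted p = 0.073 with an estimated correlation). Among them were COL1A1 (1.41 ± 0.09) and PHLDA1 (1.35 ± 0.15). Of 22 p53 targets, 12 were lower and 2 higher, 14 and 3 adjusted over the list alone (adjusted p = 0.000404; adjusted p = 0.073 with an estimated correlation). PLK2 was among them (-0.92 ± 0.07). Inflammatory genes were lower in 8 of 17 and higher in 1 (adjusted p = 0.00682; adjusted p = 0.19 with an estimated correlation). These included IL6 (-2.67 ± 0.52) and CCL2 (-1.75 ± 0.22). Neuronal genes were higher in 6 of 15 and lower in 1 (adjusted p = 0.0145; adjusted p = 0.186 with an estimated correlation), with MAP2 (1.48 ± 0.16) and L1CAM (0.97 ± 0.08). Replication-dependent histones were higher in 7 of 10 and lower in 0 (adjusted p = 0.00256; adjusted p = 0.19 with an estimated correlation). A total of 2492 genes were higher and 2732 lower; 3004 were called with length offsets, 2990 with limma on log2(TPM + 1) and 708 against a log2 change of 0.5.

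The construct lines shared part of their difference from mCherry cells. CLDN1 rose in EWS-FLI1 (2.05 ± 0.13), EWS-FLI1mut and YS37 cells, and 312 genes rose and 290 fell in both EWS-FLI1 and EWS-FLI1mut cells, where 65.5 and 60.5 would by chance. A2M (1.68 and 1.09), KRT75 (1.74 and 0.75) and IGFBP7 (1.89 and 0.65) rose in both. For EWS-FLI1 and YS37 the counts were 581 and 347 (214.9 and 170.1 by chance), with CDH5, CLDN1, MMP9 (2.27 and 1.56) and TRAF1 (1.61 and 1.77) higher and STC1 (-1.52 and -1.90) lower in both. Another 236 genes rose with EWS-FLI1 and fell with YS37 (189.8 by chance), and 153 did the opposite (192.5 by chance). EWS-FLI1mut and YS37 shared 204 rises and 144 falls (68.0 and 61.9 by chance), with NTRK2 and GDF15 (1.26 and 1.52) up and TNFAIP6 (-1.37 and -1.87) down. In this pair 79 genes rose with EWS-FLI1mut and fell with YS37 (60.1 by chance), and 85 did the opposite (70.1 by chance). Because the pairs share the mCherry libraries, their covariances of log2 fold changes were set beside simulated unchanged groups: 0.115 against 0.0472, 0.117 against 0.0466 and 0.0889 against 0.0469, in the same order. The Pearson correlations of 0.462, 0.372 and 0.335 were below the 0.505, 0.497 and 0.501 of the simulated groups, whose changes are shared noise alone. Such noise gives a correlation of this size by design, so the correlations do not gauge how much the lines share. The chance counts take no account of the shared mCherry libraries. The simulation holds no difference between lines, so mCherry cells that stand apart as a whole would also raise the covariances.

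**Figure D2:**
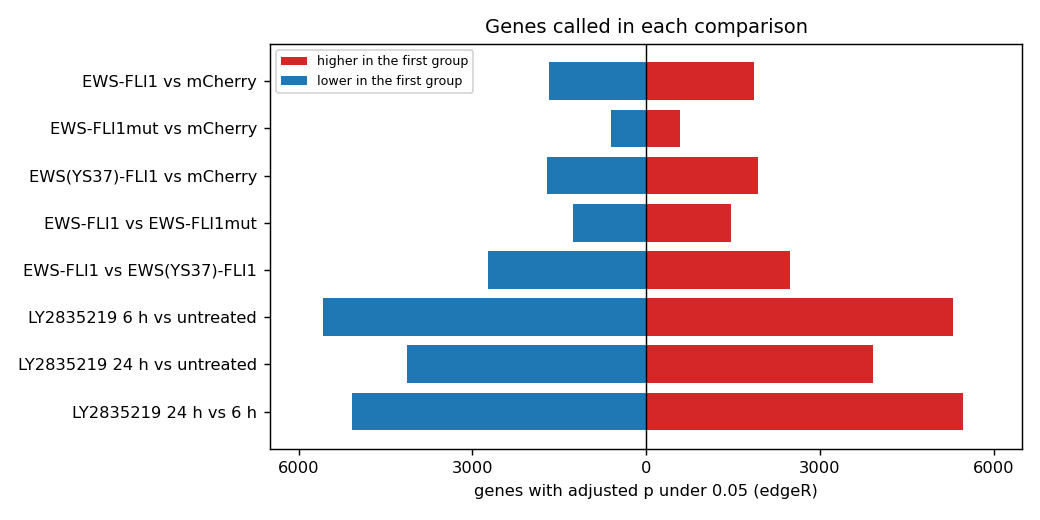
Genes with an adjusted p under 0.05 in each of the 8 comparisons (edgeR, 3 libraries per group), as bars to the right for genes higher in the first group named and to the left for genes lower. EWS-FLI1mut vs mCherry had the fewest (592 and 608) and 6 h of LY2835219 the most (5303 and 5587).

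In EWS-FLI1 cells, cell cycle genes fell and p53, inflammatory and stress genes rose at 6 h of LY2835219. MYCT1 (7.31 ± 0.27), SELPLG, the selectin ligand PSGL-1 (5.46 ± 0.31), and NPR3, a natriuretic peptide receptor (5.42 ± 0.30), rose most steeply among genes with separate libraries. MYCN (-5.45 ± 0.36), the BH3-only death gene BMF (-5.00 ± 0.19), MYOCD (-4.97 ± 0.43), the pluripotency factor SOX2 (-4.12 ± 0.20) and the ETS factor ETV1 (-4.12 ± 0.24) fell. In all, 5303 genes rose and 5587 fell, 64.9% of those tested, with 1494 and 2406 past 1 on the log2 scale; 5552 genes were called against a log2 change of 0.5. Rises made up 48.7% of the calls, 32.2% with no scaling factors and 26.2% with limma on log2(TPM + 1).

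All 37 tested E2F/G1-S genes fell at 6 h, 37 adjusted over the list alone (adjusted p = 1.2e-16). Among them were E2F1 (-2.65 ± 0.12), E2F2 (-2.84 ± 0.16) and BRCA1 (-2.60 ± 0.09). G2/M genes fell in 32 of 33, 32 adjusted over the list alone (adjusted p = 1.49e-13; adjusted p = 0.0543 with an estimated correlation). KIF11 was among them (-1.63 ± 0.07). Of 14 genes of the CDK4/6-RB machinery, 4 rose and 9 fell, 4 and 9 adjusted over the list alone (adjusted p = 0.138). Cyclin D2 (CCND2), a partner of CDK4 and CDK6, rose by 1.93 ± 0.05 and cyclin D3 (CCND3), another, fell (-1.81 ± 0.08). Of 22 p53 targets, 19 rose and 1 fell, 19 and 2 adjusted over the list alone (adjusted p = 8.5e-09). These included FAS (2.38 ± 0.16), PLK3 (2.15 ± 0.08) and CDKN1A (1.53 ± 0.06). NF-kB and inflammatory genes rose in 15 of 17 and fell in 0, 16 and 0 adjusted over the list alone (adjusted p = 3.78e-08). Among them were the protease MMP3 (4.28 ± 0.33) and BIRC3 (3.17 ± 0.15). The ATF4/integrated stress response list rose in 20 of 25 and fell in 3, 20 and 4 adjusted over the list alone (adjusted p = 1.94e-07). Examples were PPP1R15A (3.04 ± 0.07), GDF15 (2.88 ± 0.18) and SESN2 (2.01 ± 0.09).

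V-ATPase subunits, which acidify lysosomes, rose in 13 of 16 and fell in 0, 13 and 0 adjusted over the list alone (adjusted p = 3.04e-06). These included ATP6V0E1 (1.41 ± 0.08) and ATP6V1B2 (1.16 ± 0.06). Lysosomal proteins rose in 29 of 36 and fell in 1, 29 and 1 adjusted over the list alone (adjusted p = 5.39e-06; adjusted p = 0.163 with an estimated correlation). Among them were the cholesterol exporter NPC1 (1.25 ± 0.09) and CD63 (1.04 ± 0.07). Autophagy and MiT/TFE genes rose in 18 of 29 and fell in 8, 18 and 8 adjusted over the list alone (adjusted p = 0.037; adjusted p = 0.236 with an estimated correlation). RRAGC, a GTPase of the mTORC1 pathway, rose (1.96 ± 0.07), while the transcription factor MITF (-2.43 ± 0.13) and the autophagy kinase ULK1 (-1.99 ± 0.09) fell. Cholesterol genes rose in 17 of 24 and fell in 4, 17 and 4 adjusted over the list alone (adjusted p = 0.00287; adjusted p = 0.125 with an estimated correlation). HMGCS1 was among them (1.47 ± 0.08). ER chaperones rose in 13 of 16 and fell in 0, 13 and 0 adjusted over the list alone (adjusted p = 0.000646; adjusted p = 0.0973 with an estimated correlation). These included XBP1 (0.95 ± 0.06) and HSPA5 (0.87 ± 0.05). Immediate early genes rose in 8 of 13 and fell in 3, 8 and 3 adjusted over the list alone (adjusted p = 0.00644; adjusted p = 0.163 with an estimated correlation). FOSL1 was among them (3.49 ± 0.09). The lists of the Ewing sarcoma literature had no call: 7 rises and 5 falls among 17 repressed genes (adjusted p = 0.405) and 6 and 7 among 28 activated genes (adjusted p = 0.791).

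At 24 h of LY2835219 cell cycle genes were still low and V-ATPase and p53 genes still high, while cholesterol and ER chaperone genes were below untreated cells. MMP3 (4.96 ± 0.32), RCAN2 (3.74 ± 0.14), the enzyme RENBP (3.74 ± 0.27) and the lymphocyte receptor SLAMF7 (3.71 ± 0.23) rose. KIAA1210 (-6.71 ± 0.17), MYOCD (-4.45 ± 0.39), SMOC1 (-3.77 ± 0.15), cardiac troponin TNNT2 (-3.71 ± 0.19) and the collagen receptor ITGA11 (-3.65 ± 0.21) fell. In all, 3919 genes rose and 4132 fell, 48.0% of those tested, with 834 and 978 past 1 on the log2 scale; 2299 were called against a log2 change of 0.5. No untreated library is labelled as harvested beside the 6 h or 24 h libraries, and LY2835219-treated mCherry cells are not part of the design. At either time, an effect of the drug is not told apart from time in culture or a vehicle. Whether such an effect needs EWS-FLI1 is not told either.

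E2F/G1-S genes fell in 36 of 37 at 24 h, 37 adjusted over the list alone (adjusted p = 3.03e-27). E2F1 was among them (-1.86 ± 0.11). G2/M genes fell in 33 of 33, 33 adjusted over the list alone (adjusted p = 1.63e-30), with the proliferation marker MKI67 (-1.68 ± 0.07) and the mitotic kinase CDK1 (-1.47 ± 0.07). In the CDK4/6-RB machinery 9 of 14 fell and 3 rose, 10 and 3 adjusted over the list alone (adjusted p = 0.0117), with CCND2 up (2.29 ± 0.05) and CDKN1B, the CDK inhibitor p27, down (-1.29 ± 0.07). Of 22 p53 targets, 21 rose and 0 fell, 21 and 0 adjusted over the list alone (adjusted p = 1.21e-14). These included FAS (1.51 ± 0.16), TP53INP1 (1.49 ± 0.09) and ZMAT3 (1.17 ± 0.08). V-ATPase subunits rose in 13 of 16 and fell in 0, 13 and 0 adjusted over the list alone (adjusted p = 3.17e-07). Lysosomal proteins rose in 28 of 36 and fell in 5, 28 and 5 adjusted over the list alone (adjusted p = 1.42e-09; adjusted p = 0.0596 with an estimated correlation). CTSA, a protease, was among them (1.19 ± 0.07).

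Cholesterol genes fell in 19 of 24 at 24 h and rose in 1, 19 and 1 adjusted over the list alone (adjusted p = 2.02e-06). FDFT1, squalene synthase, was among them (-1.12 ± 0.06). ER chaperones fell in 14 of 16 and rose in 1, 14 and 1 adjusted over the list alone (adjusted p = 6.38e-08). These included MANF (-1.11 ± 0.07) and HSPA5 (-0.91 ± 0.05). All 8 epithelial markers fell, 8 adjusted over the list alone (adjusted p = 0.000522). KRT14 was among them (-2.99 ± 0.21). The literature's repressed list fell in 10 of 17 and rose in 3, 11 and 3 adjusted over the list alone (adjusted p = 0.000474; adjusted p = 0.112 with an estimated correlation). Examples were CTGF (-2.66 ± 0.07), CRYAB (-2.36 ± 0.08) and THBS1 (-1.52 ± 0.05). The ATF4/integrated stress response list rose in 15 of 25 and fell in 5, 15 and 5 adjusted over the list alone (adjusted p = 0.00614; adjusted p = 0.205 with an estimated correlation). DDIT4 was among them (1.44 ± 0.10). Replication-dependent histones fell in 6 of 10 and rose in 0 (adjusted p = 0.00614, and 0.205 with an estimated correlation). They fell beside the E2F/G1-S and G2/M lists, so RNA quality and cell cycle state are not told apart here. Inflammatory genes parted, 6 up and 4 down among 17 (adjusted p = 0.353): MMP3 rose and CXCL8 (-2.34 ± 0.34) and CCL2 (-1.84 ± 0.27) fell.

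Between 6 h and 24 h, 5465 genes rose and 5088 fell, 62.9% of those tested, with 5085 genes called against a log2 change of 0.5. The growth arrest gene GAS1 (3.69 ± 0.29), RFXAP (3.26 ± 0.28) and SMAD6, an inhibitor of BMP signalling (3.16 ± 0.17), rose. BCL2A1, a survival gene (-6.20 ± 0.46), NPR3 (-5.86 ± 0.31) and CXCL8 (-4.82 ± 0.33) fell. The muscle gene XIRP1, at 243 counts at 6 h, was at 0 counts at 24 h, at least 78.9-fold lower with a floor of 3 counts over the group. Inflammatory genes fell in 14 of 17 and rose in 1, 14 and 1 adjusted over the list alone (adjusted p = 9.94e-07). Cholesterol genes fell in 18 of 24 and rose in 2, 18 and 2 adjusted over the list alone (adjusted p = 2.89e-07; HMGCS1 -1.91 ± 0.08), and ER chaperones fell in 14 of 16 and rose in 0, 14 adjusted over the list alone (adjusted p = 1.05e-08; HSPA5 -1.78 ± 0.05). Immediate early genes fell in 9 of 13 and rose in 0, 9 adjusted over the list alone (adjusted p = 5.36e-05; adjusted p = 0.0664 with an estimated correlation). FOSL1 was among them (-2.99 ± 0.08). E2F/G1-S genes parted, 17 up and 10 down among 37, 18 and 10 adjusted over the list alone (adjusted p = 0.551): BRCA1 (1.63 ± 0.09) and the helicase subunit MCM3 (1.14 ± 0.05) rose and TK1 fell (-1.07 ± 0.06). The changes at 6 h and 24 h against untreated cells had a covariance of 0.432, against 0.0468 in simulated unchanged groups that share the untreated libraries. Their Pearson correlation was 0.473, within the simulated range of 0.435 to 0.532. Unchanged groups that share a control give such a correlation by design, so this comparison does not say how far the profiles agree. Untreated libraries that stand apart as a whole would also raise the covariance. They had 2191 shared rises and 2512 shared falls (1237.8 and 1375.5 by chance), among them MMP3 and SLAMF7 up and MYOCD, MYCN and BMF down.

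**Figure D3:**
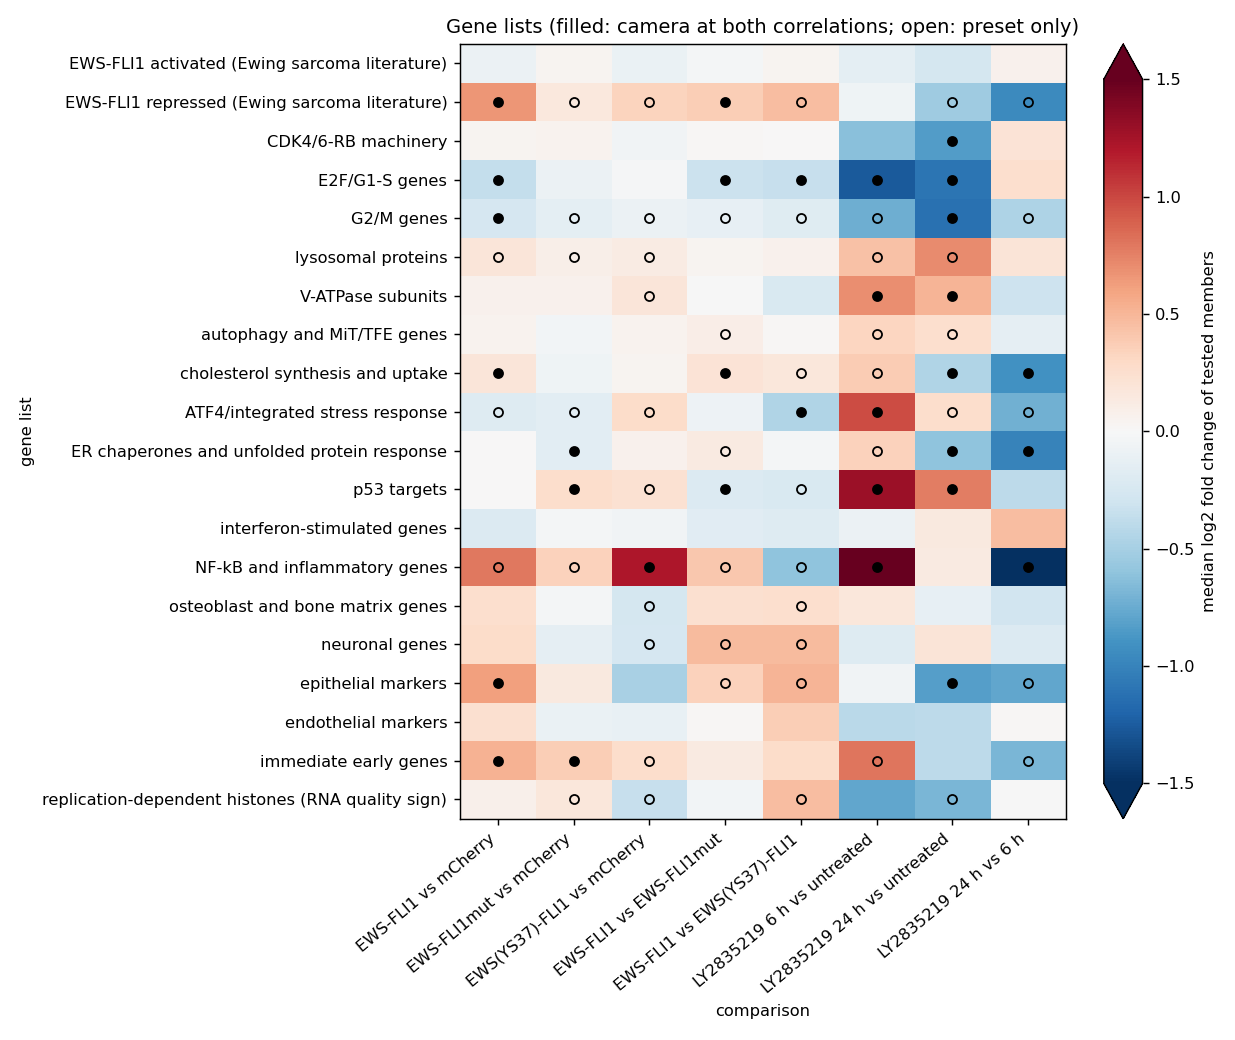
Median log2 fold change of the tested members of 20 gene lists (vertical) in the 8 comparisons (horizontal), as colour; filled circles mark a camera adjusted p under 0.05 at the preset and the estimated correlation, open circles at the preset only. E2F/G1-S genes were lower in 5 comparisons with a filled circle, and inflammatory genes rose at 6 h of LY2835219 and fell from 6 h to 24 h.

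Genes higher in EWS-FLI1 than in mCherry cells tended to fall at 24 h of LY2835219: 927 rose with EWS-FLI1 and fell with the drug (458.9 by chance), and 342 rose in both (435.3 by chance). Of genes lower in EWS-FLI1 than in mCherry cells, 585 rose with the drug (390.0 by chance) and 575 fell in both (411.2 by chance). These chance counts leave the shared EWS-FLI1 libraries out of account. KIAA1210 (1.97 ± 0.11 over mCherry and -6.71 ± 0.17 at 24 h), CDH5 (2.79 and -2.88), CD248 (2.44 and -2.70), the calcium-binding matrix gene SMOC1 (1.34 and -3.77), PHLDA2 (1.76 and -2.83) and CXCL8 (1.93 and -2.34) rose with EWS-FLI1 and fell at 24 h. The covariance of the 2 profiles was -0.141, against a mean of -0.0470 in simulated unchanged groups that share the EWS-FLI1 libraries (-0.0533 to -0.0405 over 20 draws), with a Pearson correlation of -0.319 against -0.501 in the simulation. The simulation holds noise between libraries only. Untreated EWS-FLI1 libraries that stand apart as a whole would also make the covariance more negative and add calls of opposite direction. A shared group alone gives the simulated correlation, so the 2 correlations do not gauge the reversal. At 6 h the covariance was -0.0511, within the simulated range of -0.0538 to -0.0438, with a correlation of -0.0836 against -0.497. There, 646 genes rose with EWS-FLI1 and fell at 6 h (620.5 by chance), such as CD248 (2.44 and -2.78) and EPPK1 (1.63 and -1.86), while 826 rose in both (588.8 by chance). The correlation at 6 h was -0.0311 with the stricter low-count filter and -0.196 to -0.177 leaving out each EWS-FLI1 library in turn.

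**Figure D4:**
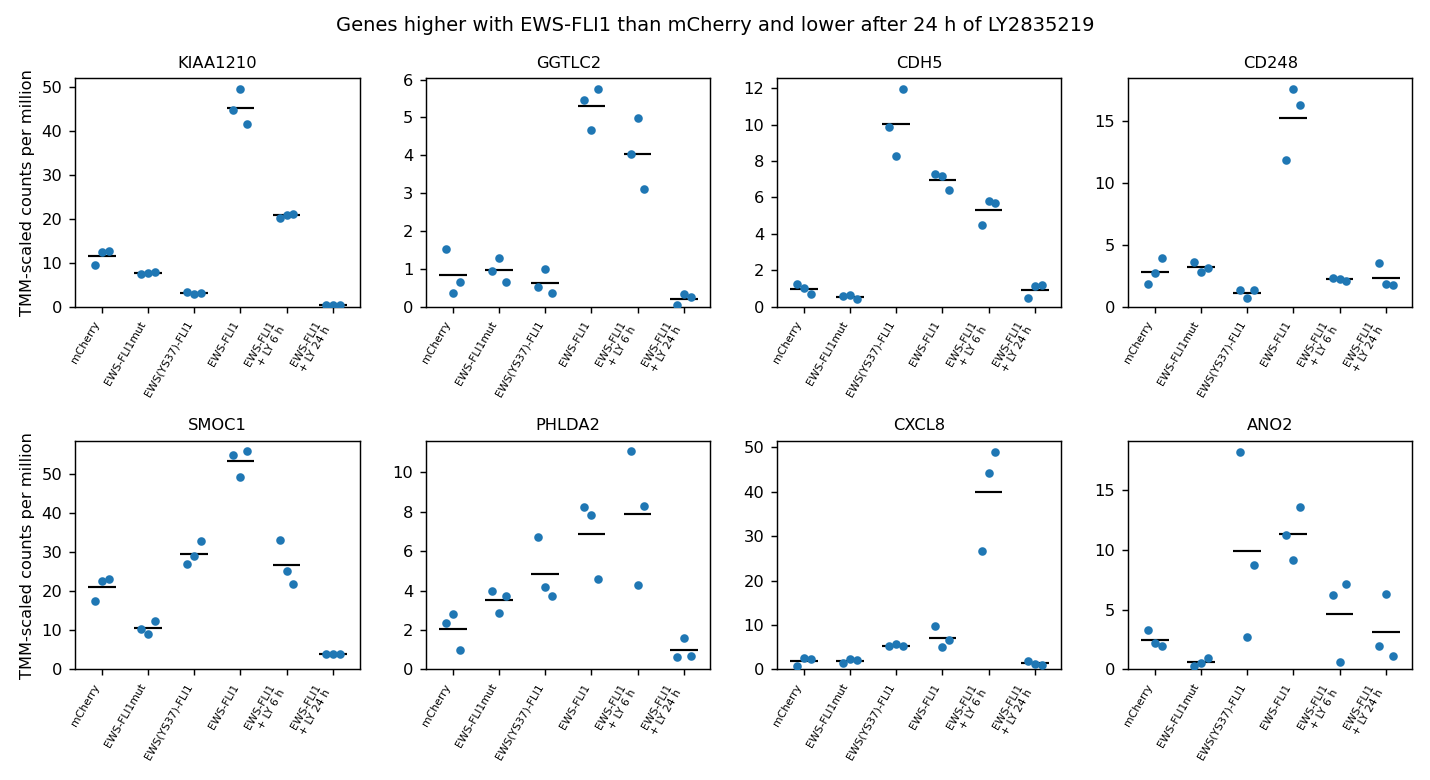
TMM-scaled CPM of 8 genes called higher with EWS-FLI1 than with mCherry and lower after 24 h of LY2835219, in the 6 groups, with 1 point per library and a line at the mean of 3. CD248 fell by 6 h (log2 -2.78), whereas CXCL8 rose at 6 h before falling below its untreated level.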

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

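The tests of transgene level, of sample labels, of the mCherry libraries, of scaling and of time in culture were chosen only after the results they concern were seen. The results in the next 3 paragraphs are pairs of effects of opposite direction, each called (lists at the preset correlation), whose difference was itself tested with edgeR or, for lists, with camera.

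Members of the inflammatory and immediate early lists were above untreated cells at 6 h of LY2835219 and below them at 24 h, while the inflammatory list as a whole had 6 genes up and 4 down of 17 at 24 h (adjusted p = 0.353) and MMP3 was still up (4.96). CXCL8 went from log2 2.48 to -2.34 (difference -4.82, adjusted p = 1.2e-11), CCL2 from 2.93 to -1.84 (-4.76, adjusted p = 1.43e-13), CCL20, a chemokine, from 2.78 to -1.48 (-4.25, adjusted p = 8.51e-10) and CSF2, the cytokine GM-CSF, from 3.10 to -1.02 (-4.12, adjusted p = 6.13e-10). The immediate early gene NR4A1 went from 1.10 to -1.55 (-2.65, adjusted p = 4.27e-17). The fall of CCL20 at 24 h was not called with length offsets (adjusted p = 0.146).

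Between EWS-FLI1 and EWS(YS37)-FLI1, each against mCherry, CD248 differed by 3.76 (2.44 and -1.32, adjusted p = 1.73e-09), ITGA11 by 3.40 (1.04 and -2.36, adjusted p = 2.07e-11) and the basal keratin KRT5 by 2.29 (1.16 and -1.14, adjusted p = 4.83e-06). Between EWS-FLI1 and EWS-FLI1mut, CCL2 differed by 2.21 (1.01 and -1.20, adjusted p = 5.5e-06). The call of KRT5, EWS(YS37)-FLI1 vs mCherry, was lost without mCherry replicate 1 (adjusted p = 0.0625) or YS37 replicate 2 (0.0503). The call of CCL2, EWS-FLI1mut vs mCherry, was lost without EWS-FLI1mut replicate 1 (0.0969) or 2 (0.0865) or mCherry replicate 2 (0.0707) or 3 (0.103). With length offsets the YS37 falls of KRT5 (adjusted p = 0.547) and ITGA11 (0.373) and the rise of KRT5 with EWS-FLI1 (0.349) were not called. The ATF4/integrated stress response list had a median of -0.19 with EWS-FLI1 and 0.27 with YS37, and a median difference of -0.45 in the direct comparison (adjusted p = 2.02e-10). With EWS-FLI1mut its median was -0.15 (adjusted p = 0.00504). With an estimated correlation the list was not called with EWS-FLI1 (adjusted p = 0.183), EWS-FLI1mut (adjusted p = 0.319) or YS37 (adjusted p = 0.106).

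The cholesterol and ER chaperone lists were higher at 6 h and lower at 24 h of LY2835219: medians of 0.38 and -0.46 for cholesterol genes (direct median -0.91, adjusted p = 2.89e-07) and 0.35 and -0.60 for ER chaperones (-0.999, adjusted p = 1.05e-08). The rises at 6 h were not called with an estimated correlation (adjusted p = 0.125 for cholesterol genes and adjusted p = 0.0973 for ER chaperones). The choice among 4 scalings was argued against as the cause of the fall at 24 h, where the highest median of the 2 lists was -0.42. Its standard error was 0.074 over the members, taken as independent. The 4 scalings hardly differed at 24 h (medians of all genes from 0.016 to 0.065), and none would show a change in total RNA. For the rise at 6 h an effect of scaling stays open, because the lowest median, that of ER chaperones with no scaling factors, was 0.10 with a standard error of 0.083. Time in culture cannot be told apart from the drug at 6 h or 24 h, because 0 untreated libraries carry a stated later time. No biological explanation was tested.

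The literature's repressed list was higher with EWS-FLI1 than with mCherry, the opposite of its name. A swap with an mCherry sample was argued against by FLI1, whose lowest level in the EWS-FLI1 libraries was 200.4 times its highest in the mCherry libraries. FLI1 was also high with EWS-FLI1mut (642 CPM) and YS37 (1019 CPM), so this ratio cannot exclude a swap of labels between constructs. Not all of the rise rested on the mCherry libraries standing apart, since the list was also higher than with EWS-FLI1mut (camera p = 0.00611 with an estimated correlation). Its median was 0.37 there and 0.66 over mCherry. Over mCherry the list also rose at the preset correlation with EWS-FLI1mut (median 0.16) and YS37 (0.33). Part of the rise may therefore come from the mCherry libraries. A low transgene level could contribute: FLI1 RNA with EWS-FLI1 was 0.243 times that with EWS(YS37)-FLI1, and since level and construct change together the 2 cannot be told apart. The list comes from work in other cells, and whether U2OS responds differently was not tested.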

How the results depend on the processing

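The fit with no scaling factors and the fit without the most abundant genes were chosen after seeing the data. Of 160 gene list results, 82 were called at the preset correlation, and with an estimated correlation 50 of these lost their call and 0 others gained one. By fry 4 calls were lost and 37 gained, and its mixed test, which has no direction, lost 1 and gained 75; the replicate block changed 0. Leaving out 1 library at a time, 20 of 960 results lost and 14 gained a call. Of 14866 alternative results for named genes, 13949 kept direction and side of the threshold, 910 lost and 3 gained a call and 4 reversed. Of the 910 losses, 298 (of 784 results) came with glmTreat, 126 with limma on log2(TPM + 1), 122 with length offsets and 300 (of 4704) without 1 library. The 4 were NPC1 with YS37 by limma on log2(TPM + 1) (-0.020), KRT8 at 6 h by the same (-0.058), and KRT18 at 6 h by the same (-0.26) and with no scaling factors (-0.13); the cause was not tested. Of 16 transgene ratios taken as mean TPM, 9 moved by more than the spread between replicates and 7 did not; the replicate block was not run on these ratios, only on the fitted fold changes of FLI1 and EWSR1.

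Against a log2 change of 0.5 (glmTreat), which asks for a larger effect by construction, the counts of called genes (past 1 in brackets) were 183 (126) for EWS-FLI1 vs mCherry, 29 (21) for EWS-FLI1mut, 404 (283) for YS37, 192 (140) for EWS-FLI1 vs EWS-FLI1mut, 708 (481) for EWS-FLI1 vs YS37, 5552 at 6 h, 2299 at 24 h and 5085 for 24 h vs 6 h. With length offsets they were, in the first 5 comparisons, 1696, 359 (38), 1965, 1264 and 3004, and with limma on log2(TPM + 1) 1679 (124), 384 (32), 1907 (236), 1276 (155) and 2990 (382), with 1083 past 1 at 24 h; the cause was not tested. Without a low-count filter 171 genes were past 1 for EWS-FLI1mut vs mCherry. Leaving out each library in turn gave 667 to 1011 calls for EWS-FLI1mut vs mCherry, and 58 to 80 past 1, where fewer libraries were tested.

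The correlation of EWS-FLI1 and LY2835219 profiles was -0.0311 (6 h) and -0.292 (24 h) with the stricter filter, -0.0666 and -0.366 over genes called in either, and -0.196 to -0.177 and -0.443 to -0.428 leaving out a shared library, where fewer shared libraries add shared noise. Genes called in either gave 0.493, 0.391 and 0.370 for the construct pairs and 0.498 for 6 h with 24 h; the stricter filter gave 0.354 for EWS-FLI1 with YS37 and 0.304 for EWS-FLI1mut with YS37. Without a shared library the ranges were 0.562 to 0.586, 0.483 to 0.495, 0.484 to 0.502 and 0.505 to 0.520. At these depths edgeR called 61% of simulated 1.5-fold changes.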

Other observations

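The gene families were chosen after the main results were seen, as was the test without the most abundant genes, while the tests of length, of genomic span and of other splits were written before. Genes of the HOX clusters, which set position along the body axis, fell together at 6 h of LY2835219 and came back by 24 h. At 6 h, 26 of 34 fell and 2 rose (camera adjusted p = 6.74e-05; adjusted p = 0.0562 with an estimated correlation; median -1.19, and -1.43 with no scaling factors), with HOXD9 (-2.84 ± 0.20) and HOXA13 (-2.77 ± 0.31). From 6 h to 24 h, 29 rose and 2 fell (adjusted p = 2.22e-05, and 0.0342 with an estimated correlation), HOXA13 by 2.83 ± 0.31, and against untreated cells 4 were higher and 7 lower at 24 h, with HOXB6 at 0.70 ± 0.12. In EWS-FLI1 cells HOXB2 was lower than in mCherry cells (-1.03 ± 0.15), and against EWS-FLI1mut 9 HOX genes were lower and 0 higher (adjusted p = 0.0537 with an estimated correlation).

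Genes of the cytoplasmic ribosome were higher under LY2835219. Of 84 cytoplasmic ribosomal proteins, 78 rose and 2 fell at 6 h (adjusted p = 5.41e-20; adjusted p = 0.285 with an estimated correlation; median 0.59, and 0.35 with no scaling factors), such as RPL9 (1.38 ± 0.07), and 77 rose and 1 fell at 24 h (adjusted p = 1.24e-20; adjusted p = 0.32 with an estimated correlation). All 13 mitochondrially encoded proteins rose at 6 h (adjusted p = 7.83e-06; adjusted p = 0.285 with an estimated correlation), with MT-ND4 (0.71 ± 0.07), and 28 of 37 proteasome subunits rose and 2 fell (adjusted p = 7.83e-06; adjusted p = 0.236 with an estimated correlation), with PSMD12 (0.93 ± 0.06). At 24 h proteasome subunits had 8 rises and 9 falls (adjusted p = 0.95). Complex I subunits rose in 20 of 35 and fell in 3 at 6 h (adjusted p = 0.0105; adjusted p = 0.435 with an estimated correlation) and rose in 7 at 24 h (adjusted p = 0.3). Mitochondrial ribosomal proteins were lower with EWS-FLI1 than with YS37 in 38 of 77 and higher in 0 (adjusted p = 2.08e-10, and 0.0168 with an estimated correlation). Against mCherry they were lower with EWS-FLI1mut in 13 and higher in 0 (adjusted p = 1.55e-12, and 0.00773 with an estimated correlation), lower with EWS-FLI1 in 22 and higher in 1 (adjusted p = 8.74e-07; adjusted p = 0.0529 with an estimated correlation), and higher with YS37 in 11 and lower in 1 (adjusted p = 0.0229; adjusted p = 0.372 with an estimated correlation). Collagens rose with EWS-FLI1 over mCherry in 17 of 38 and fell in 2 (adjusted p = 4.48e-06; adjusted p = 0.0529 with an estimated correlation), with the basement membrane chain COL4A4 (1.15 ± 0.14) and COL22A1 (1.06 ± 0.14). Keratins fell in 12 of 20 and rose in 1 at 24 h (adjusted p = 0.00201; adjusted p = 0.188 with an estimated correlation), with KRT75 falling from 6 h to 24 h (-2.29 ± 0.09), and the Kruppel-like factors had 7 rises and 3 falls among 15 at 6 h (adjusted p = 0.161), with KLF6 up (1.96 ± 0.09). Over mCherry these factors had 6 rises and 0 falls with EWS-FLI1 (camera adjusted p = 0.000889, and 0.0529 with an estimated correlation). With EWS-FLI1mut they had 2 and 0 (0.00705 and 0.0865), and with YS37 4 and 1 (0.0863 at the preset correlation).

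After 6 h of LY2835219, 64.9% of genes were called against untreated cells, and part of that change was gone at 24 h. A few genes did not take most of the counts: the 10 most abundant held 7.93% at 6 h and 6.39% in untreated EWS-FLI1 cells. Without mitochondrial genes and the 100 genes with the most counts, 10799 genes were called. That fit again used TMM factors, which already limit the effect of a few genes, so its count cannot decide. A shift of most RNAs at once was not tested. Against transcript length and GC content bias, both together explained 0.774% of the variance of the 6 h changes. The hypothesis that genes with a long genomic span fell at 6 h, which a slowed elongation may produce, had a Spearman correlation of -0.103 after length and GC content were removed, just past the bound of -0.1 set for it. In the 4193 genes of shortest span (median span 5.08 kb) the median change was 0.06 with 27.9% falling, and in as many of the longest span (143 kb) it was -0.23 with 44.0% falling, so span goes with at most a small part of the change. The correlation was -0.0651 at 24 h. In comparisons without the drug it was 0.0839 (EWS-FLI1 vs mCherry), 0.0686 (EWS-FLI1 vs YS37) and 0.0627 (EWS-FLI1 vs EWS-FLI1mut). These share the untreated EWS-FLI1 libraries with the 6 h comparison, at the opposite sign, so they give no independent background. Without those libraries the correlation was 0.0427 (EWS-FLI1mut vs mCherry) and 0.00206 (YS37 vs mCherry). The hypothesis stays open.

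Each comparison was also fitted on its 6 libraries alone and on the other splits of these into 3 and 3; with 10 splits, 1 of them real, no share under 0.05 can arise. The real split and the highest other called 3304 and 2 genes for EWS-FLI1 vs mCherry, 1251 and 1 for EWS-FLI1mut, 3339 and 1 for YS37, 2974 and 1 for EWS-FLI1 vs EWS-FLI1mut, 4967 and 0 for EWS-FLI1 vs YS37, 10602 and 0 for LY2835219 at 6 h, 7698 and 1 at 24 h, and 10248 and 0 for 24 h vs 6 h.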
